A study of Mus musculus with 3 samples.

How the data were processed

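RNA from NMuMG cells, an epithelial line of the mouse mammary gland, was measured on 3 Affymetrix GeneChip arrays. Per the labels' protocols, cells were grown in D-MEM with serum and puromycin, total RNA was extracted with ISOGEN, and biotin-labelled DNA was made from 100 ng of it with the Ambion WT Expression Kit. Per the labels, 1 array held cells with the pCAGIP vector (mock, n = 1) and 2 held stable clones with FLAG-tagged MafK in that vector, clone 4 and clone 10 (MAFK, n = 2). The labels do not say whether the clones were grown or extracted apart, so p-values measure only the spread between these 2 arrays.

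The deposited values are log2 expression per probe set, made by the authors with RMA per the submitters' processing notes, with no version given. RMA corrects the background, quantile normalizes the arrays and summarises the probes of a set by median polish. The values ran from 4.40 to 14.3 with medians of 6.89, 6.92 and 6.93, as log2 intensities do. No filter, pooling or genome build is given in the sources used here, and no detection p-values were used. Fold values given here are 2 to the power of a difference of log2 RMA values.

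Median polish over 3 arrays can return equal values for many probe sets. On all 3 arrays 10337 of 28815 probe sets (35.9%) had the same value, and 16233 (56.3%) had the same value in both clones. Among genes, 11062 of 19935 (55.5%) were equal in the clones, so that their only residual degree of freedom gave a variance of 0.

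Probe sets were named through the platform's annotation. Of 28815 probe sets, 21780 had 1 gene symbol, 1605 had several and 5430 had none, and the last 2 kinds were not named. Symbols were updated by Entrez identifier through a gene table of assembly GRCm38.p6, used for names and for the chromosome of each gene, which matched 21689 probe sets and left 91 under the older symbol. The probe set with the highest mean over the arrays stood for each gene. No coordinates are given.

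Sizes were taken as log2 differences from mock in each clone, and a gene counted as apart where both clones differed by at least 2-fold in the same direction. The planned test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on all 3 arrays, with 1 residual degree of freedom per gene, which assumes that mock varies as the clones do. Coefficients and residual SDs below 1e-08 were set to 0, and genes with no difference were given a p of 1. Because most variances were 0, the planned prior had 0.949 degrees of freedom and an added limma fit was run after the data were seen. It took the prior (1.93 degrees of freedom, SD 0.0694) from the 8873 genes whose clones differed and applied it to all genes. Genes equal in the clones still entered with a variance of 0 and so had the smallest standard error, 0.0690. "Rose" and "fell" are used for genes at least 2-fold apart in both clones and past this added test, and the standard errors given are its own.

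The script was tested on simulated data of 19935 genes with 200 changed in both clones. Changes of 0.5, 1.5 and 2.5 on the log2 scale were recovered by the added limma fit in 0%, 74.5% and 96.5% of genes, with 0, 9 and 42 false calls. The 2-fold rule recovered 2%, 96% and 100% with 28, 25 and 49 false calls, and limma as planned recovered 89.5%, 96% and 99% with 3913, 4033 and 4137 false calls. A simulated shift of 0.5 in a list of 45 genes lay at percentile 100, and 1 of 20 other lists was called. Median polish was simulated on 4000 probe sets of 25 probes with a noise SD of 0.2. Agreement between the clones was set beside 100 simulations of unchanged clones that share 1 mock array.

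Gene lists were fixed before the data were examined: 21 lists with 582 symbols, of which 542 were matched. They were epithelial, mesenchymal, epithelial-mesenchymal transition factor, NRF2, MAF and CNC family, TGF-beta, lysosome, proliferation, interferon, basement membrane, cholesterol, glycolysis, unfolded protein, p53, inflammatory, heme and iron, luminal, basal, fibroblast, endothelial and immune lists, some sharing members. Each list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. A list was said to stand apart where its median lay outside percentiles 2.5 to 97.5 in both clones and in the same direction. A rule set beforehand named Mafk, Gpnmb, Cdh1 and Hmox1, the 12 largest increases and decreases by the smaller of the clones' differences (among genes whose higher value reached the median of all probe sets, without predicted genes, receptors of smell, small RNAs and immune receptor segments), and up to 4 members of each list. Other list members at least 2-fold apart in both clones, genes named between the clones and X-linked genes were named after their values were seen.

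Alternatives tried were an intensity trend or robust estimation in eBayes, treat at a fold of 1.2, an unadjusted p, a second quantile normalization, centring on the array median, leaving out low genes, other ways to join probe sets, fold thresholds of 1.5 and 3, each clone left out, and unmatched random lists. Added after the data were seen were the limma fits on or with the prior of genes whose clones differed, list means, and leaving out chromosomes 8, 14 and X. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.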

Results

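Gene expression was measured on 3 Affymetrix GeneChip arrays in NMuMG cells, an epithelial line from the mouse mammary gland. MAFK is a small MAF protein, a basic leucine zipper factor that binds DNA alone or with CNC family partners and lacks a transactivation domain of its own. One array held cells carrying the empty pCAGIP vector (mock, n = 1). Per the labels, 2 arrays held stable clones with FLAG-tagged MAFK in that vector, 1 from clone 4 and 1 from clone 10 (MAFK, n = 2). Each array gave log2 RMA values for 28815 probe sets, with medians of 6.89 in mock, 6.92 in clone 4 and 6.93 in clone 10, and 19935 genes could be compared. The number of arrays limits the precision: the mock cells were measured once, so their own spread is unknown, and the spread between the 2 clones stands in for it. Clones 4 and 10 are clonal lines, whereas the labels do not call the mock cells a clone, so differences between MAFK and mock include any that arose during cloning.

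The comparison of MAFK with mock addressed which genes differ in epithelial clones labelled as carrying FLAG-tagged MAFK, including those that mark the passage from an epithelial to a mesenchymal state. Gpnmb, which encodes a transmembrane glycoprotein, was 47.5-fold higher with MAFK, at 12.39 ± 0.10 (SD, n = 2) against 6.82 in mock on the log2 scale. Cdh1, the gene of the epithelial adhesion molecule E-cadherin, was 24.3-fold lower, at 6.75 ± 0.15 (SD, n = 2) against 11.35. Fibronectin (Fn1) was 4.28-fold higher, though of the 42 mesenchymal genes measured 4 were at least 2-fold higher in both clones and 6 lower. The chemokine gene Cxcl5 was 43.3-fold lower. The long noncoding RNA Xist, which coats the silenced X chromosome, had the largest difference among the named genes, 76.8-fold lower, at 5.48 ± 0.06 (SD, n = 2) against 11.74. Across all genes, 598 were at least 2-fold apart from mock in the same direction in both clones, 237 higher and 361 lower. Of these, 516 lie outside chromosomes 8, 14 and X, a count added after the data were seen. It does not set aside every chromosome-wide shift, since the mean differences of several other chromosomes were also shifted in both clones.

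Of these 598 genes, 80 rose and 152 fell, where a gene is said to rise or fall if it was at least 2-fold apart in both clones and passed limma's moderated test at an adjusted p under 0.05. The adjusted p-values given for single genes, and the counts adjusted over a list alone, come from a limma fit whose prior was estimated from the genes whose clones differed, a choice made after the data were seen, because 55.5% of genes had the same value in both clones. All 232 of these genes also passed limma as planned, which called 3553 genes, 2240 higher and 1313 lower. The other 366 genes at least 2-fold apart in both clones did not pass and are given by their values. In the fit used for single genes, those with the same value in both clones had the smallest standard error (0.0690). Such ties therefore still favoured passing, as for Itgb4, Itgb6, Ccng1 and Irf9. The planned count cannot be read as a count of changed genes, since 2143 of its genes had equal values in the clones and 1857 differed from mock by less than 1.2-fold, and data simulated with 200 changed genes gave between 3913 and 4137 false calls. In the same simulations the fit used for single genes gave 0, 9 and 42 false calls at log2 changes of 0.5, 1.5 and 2.5. These exceeded the share that an adjusted p under 0.05 allows slightly at a change of 1.5 and by far at 2.5. Some genes said to rise or fall may thus be false calls.

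The genes with the largest increases encode proteins of varied function. Fscn1, which encodes the actin-bundling protein fascin, rose 42.4-fold to 12.28 ± 0.17 (SD, n = 2) from 6.87, with a limma adjusted p of 0.0256. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose 43.7-fold, and the water channel gene Aqp1 rose 28.8-fold. Gpnmb had a limma adjusted p of 0.0256, Scd1 of 0.0346 and Aqp1 of 0.0256. Adgre5, an adhesion G protein-coupled receptor also known as CD97, rose 21.0-fold and the thrombin receptor gene F2r rose 18.1-fold. Nlrp2, the dynein light chain gene Dynlt3, Praf2 and Smpdl3b rose between 12.2-fold and 16.2-fold and Cytip by 4.08 on the log2 scale, with Smpdl3b at the edge of the threshold (limma adjusted p = 0.0499). Dab2, an endocytic adaptor, was 18.0-fold higher (3.90 in clone 4 and 4.43 in clone 10 on the log2 scale) but did not pass (limma adjusted p = 0.0543).

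The largest decreases were also in genes of varied function. Besides Xist, Cxcl5 and Cdh1, the 12 genes named by rank were Fundc2, which fell 33.4-fold, Ctsh (the lysosomal protease cathepsin H) at 29.4-fold, the collagenase gene Mmp13 at 25.7-fold, and the chemokine gene Ppbp at 22.8-fold. The uroplakin gene Upk1b fell 22.6-fold, Slc44a3 21.3-fold, Vat1l 19.8-fold, Wfdc2 15.3-fold and the bicarbonate cotransporter gene Slc4a4 14.1-fold. Xist and Fundc2, like Dynlt3 and Praf2 among the increases, are X-linked, and 33 of 739 X-linked genes were at least 2-fold apart from mock in both clones. Limma adjusted p-values of these 12 genes ran from 0.0256 for Xist to 0.0361 for Ppbp. With a second quantile normalization of the arrays the planned limma test no longer passed for Scd1 (adjusted p = 0.0606), Adgre5 (0.0505), Smpdl3b (0.0720), Ppbp (0.0629) or Slc44a3 (0.0600), nor, with low genes left out, for these 5 genes and Mmp13 (0.0539), with the direction kept. Many of the lower values in these pairs lie well below the array medians, where RMA compresses differences, so the folds describe these arrays on the RMA scale.

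**Figure D1:**
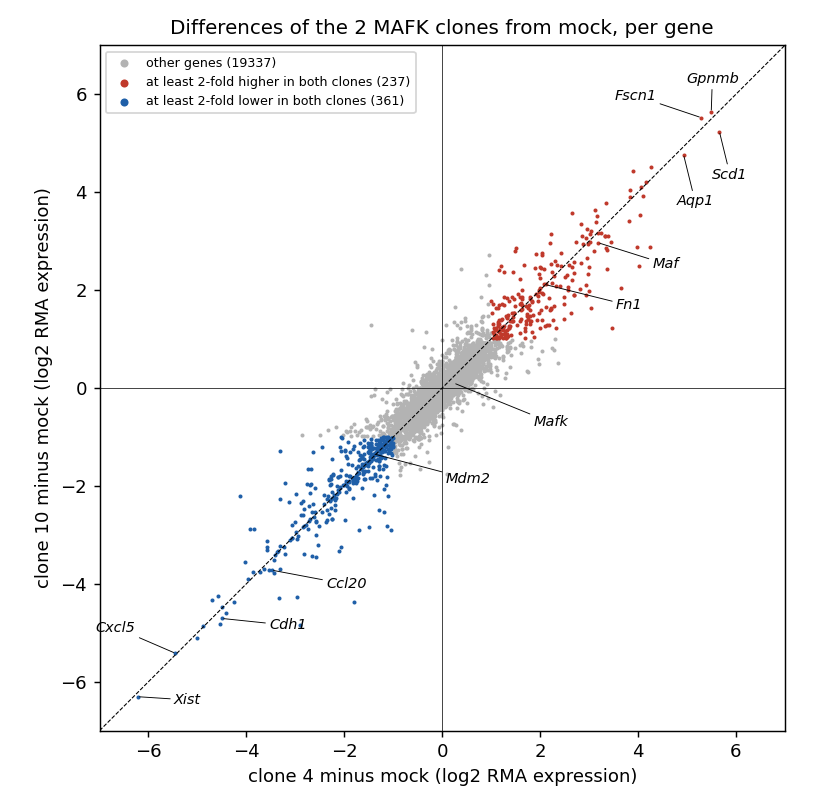
Log2 difference from mock in clone 4 (horizontal axis) and in clone 10 (vertical axis) for each of 19935 genes, with 1 point per gene and the dashed line marking equal differences. The 237 genes at least 2-fold higher in both clones (red) and the 361 at least 2-fold lower (blue) lie along that line, with Gpnmb at 5.50 and 5.64 and Xist at -6.22 and -6.31.

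The probe set for Mafk itself read 8.49 in mock, 8.74 in clone 4 and 8.59 in clone 10, a difference of 0.17 ± 0.10 (SE) on the log2 scale with a limma adjusted p of 0.612. Which part of the transcript these probes cover, and whether they match the transgene, was not analysed here, so the value is no check of the transgene. Hmox1, the heme oxygenase gene that MAFK is known to repress together with BACH1, read 8.56 on all 3 arrays. Maf, a large MAF transcription factor gene, rose 8.44-fold to 11.17 ± 0.16 (SD, n = 2) from 8.09 (limma adjusted p = 0.0346). Maf was the 1 member of the 13 measured MAF and CNC family genes to rise or fall, and 1 passed limma adjusted over the list alone. With a second quantile normalization the planned limma test gave Maf an adjusted p of 0.0580.

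Epithelial genes were lower in part. Of 45 measured members of the epithelial list, 3 fell and none rose: Cdh1, the tight junction scaffold gene Tjp1 (2.79-fold) and the desmosomal plakophilin gene Pkp1 (2.36-fold). The tricellular junction gene Lsr was 5.43-fold lower (limma adjusted p = 0.0517) and Pkp2 was 3.21-fold lower (limma adjusted p = 0.138), neither passing. The other 40 members were not 2-fold apart in both clones, and 9 members passed limma adjusted over the list alone. The median difference of the list was 0 in both clones, while its mean was -0.29 in clone 4 and -0.36 in clone 10, at percentiles 0.03 and 0.01. With low genes left out the median was -0.38 in clone 4 and -0.54 in clone 10, below all matched random lists.

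Mesenchymal genes moved in both directions. Of 42 measured members, 2 rose, the receptor gene Pdgfrb (10.1-fold, limma adjusted p = 0.0461) and Fn1 (limma adjusted p = 0.0311), and 1 fell, the matrix metalloproteinase gene Mmp3 (3.99-fold). Fstl1 was 10.4-fold higher (limma adjusted p = 0.0677) and Loxl1 was 4.28-fold higher (limma adjusted p = 0.187) without passing. Dcn, S100a4, Mmp14, Tnc and Ncam1 were each at least 2-fold lower in both clones without passing, by 3.91-fold, 4.60-fold, 3.01-fold, 2.71-fold and 3.10-fold. The list's median was 0 in both clones, its mean was -0.13 in clone 4 and 0.08 in clone 10, and 7 members passed limma adjusted over the list alone. Pdgfrb did not pass the planned limma test after a second quantile normalization (adjusted p = 0.0717).

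Among 19 measured transcription factors of epithelial-mesenchymal transition, 1 rose and none fell. Sox9 rose 3.97-fold to 10.30 ± 0.11 (SD, n = 2) from 8.32 (limma adjusted p = 0.0430), and it was also the 1 member that passed limma adjusted over the list alone. Snai1, which encodes the repressor SNAIL, was lower by -0.74 in clone 4 and -0.41 in clone 10 on the log2 scale (limma adjusted p = 0.297). The remaining 18 members were not 2-fold apart in both clones. After a second quantile normalization Sox9 had an adjusted p of 0.0610 in the planned limma test.

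Few TGF-beta response or basement membrane genes fell. Of 34 measured TGF-beta response genes, 2 fell, the integrin gene Itgb6 (4.72-fold) and the feedback inhibitor gene Pmepa1 (2.34-fold), and none rose. The list's median difference was -0.04 in clone 4 and -0.01 in clone 10, at percentiles 0.210 and 0.660 of 10000 random lists matched on expression. Random medians crowd near 0 because many genes had equal values on all arrays, so these percentiles do not show a sizeable shift. The list's mean was -0.23 in clone 4 and -0.17 in clone 10, at percentiles 0.59 and 2.46, and 3 members passed limma adjusted over the list alone. Of 29 basement membrane, integrin and hemidesmosome genes, 2 fell, Itgb4 (4.90-fold) and the laminin gene Lamb3 (3.14-fold). The laminin gene Lamb1 was 4.62-fold higher (limma adjusted p = 0.0542) and the hemidesmosome gene Dst was 2.16-fold lower (limma adjusted p = 0.0964) without passing. The list's median was 0 in both clones, at percentiles 40.8 and 43.9, and 5 members passed limma adjusted over the list alone.

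Targets of the transcription factor p53 were lower as a group. Of 21 measured members, 10 were at least 2-fold lower in both clones, none was 2-fold higher, and 4 fell. The 4 were Eda2r, an X-linked receptor gene (7.06-fold), the cyclin G1 gene Ccng1 (3.73-fold), Trp53inp1 (3.67-fold) and Mdm2, which encodes the ubiquitin ligase of p53 (2.60-fold). The other 6, Polk, Phlda3, Tnfrsf10b, Ak1, Btg2 and Zmat3, were between 2.14-fold and 2.88-fold lower without passing. The median difference was -1.01 in clone 4 and -0.77 in clone 10, below all matched random lists, 17 members lay below mock in both clones against 1 above, and 17 passed limma adjusted over the list alone. With low genes left out the planned limma test gave Trp53inp1 an adjusted p of 0.0561.

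Inflammatory and interferon-stimulated genes were lower in part. Of 32 measured inflammatory and chemokine genes, 5 fell and none rose: Cxcl5, the acute-phase gene Saa3 (12.8-fold), the chemokine genes Ccl20 (12.1-fold) and Ccl7 (4.92-fold), and the cyclooxygenase gene Ptgs2 (-3.59 in clone 4 and -3.32 in clone 10 on the log2 scale). The adhesion molecule gene Vcam1 was 13.8-fold lower (limma adjusted p = 0.0542) and Cxcl1 was 2.49-fold lower (limma adjusted p = 0.0731) without passing, and 8 members passed limma adjusted over the list alone. This list's median was 0 in both clones because 11 of its members had equal values on all arrays, and its mean was -0.68 in clone 4 and -0.80 in clone 10. With low genes left out the median was -0.05 in clone 4 and -0.45 in clone 10, at percentiles 1.49 and 0. Of 31 interferon-stimulated genes, 3 fell, Usp18 (3.87-fold), Ifit3 (-1.85 on the log2 scale) and Irf9 (2.42-fold, with the same value in both clones). Ifit1 was 6.38-fold lower (limma adjusted p = 0.0528) and Cxcl10 3.14-fold lower (limma adjusted p = 0.103) without passing. In the opposite direction Ifih1, which encodes a sensor of viral RNA, was 3.21-fold higher (limma adjusted p = 0.232). The interferon list's median was -0.02 in clone 4 and -0.10 in clone 10, below all matched random lists in both, whose medians crowd near 0. The interferon list's mean was -0.33 in clone 4 and -0.45 in clone 10, at percentiles 0.21 and 0.01, and 12 members passed limma adjusted over the list alone. With a second quantile normalization Ccl20 did not pass the planned limma test (adjusted p = 0.0556).

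Proliferation genes were slightly higher as a group, with no member 2-fold apart in both clones. Of 34 measured members, 24 lay above mock in both clones and 2 below. The median difference was 0.20 in each clone, above all matched random lists, and 11 members passed limma adjusted over the list alone. The centromere gene Cenpa had the largest difference, 0.94 in clone 4 and 1.08 in clone 10 on the log2 scale (limma adjusted p = 0.0806), followed by Bub1 at 0.62 and 0.66 (limma adjusted p = 0.0950). Over all genes no member passed the added limma fit, and 12 passed limma as planned.

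Antioxidant response genes, many of them targets of NRF2, a CNC factor that binds DNA as a partner of small MAF proteins, included members apart in both directions, with 19 below mock in both clones and 10 above. Of 39 measured members, 2 rose, Ptgr1 (3.17-fold) and the carbonyl reductase gene Cbr1 (2.32-fold), and 1 fell, the epoxide hydrolase gene Ephx1 (7.35-fold). Osgin1 was 2.12-fold higher without passing (limma adjusted p = 0.0766). The glutathione transferase genes Gstm2, Gstp1 and Gsta4 were 6.64-fold, 5.97-fold and 5.07-fold lower, and Abcc4, Slc7a11 and Aldh3a1 were 3.29-fold, 2.96-fold and 2.37-fold lower, none passing. Another 29 members were not 2-fold apart in both clones. Of all members, 9 had equal values on all arrays, among them Hmox1, Nqo1, Gclc and Txnrd1. The list's median was -0.05 in clone 4 and 0 in clone 10, its mean was -0.38 and -0.32, each at percentile 0.01, and 14 members passed limma adjusted over the list alone. The median lay below percentile 2.5 in both clones after a second quantile normalization (-0.03 and -0.02), with low genes left out (-0.11 and -0.10) and without chromosomes 8, 14 and X (-0.07 and -0.04). Random medians crowd near 0, so these percentiles do not show a sizeable shift of the list. In the planned limma test after a second quantile normalization Ephx1 had an adjusted p of 0.0683.

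The remaining metabolic and stress lists had few members apart from mock. Gpnmb was the 1 member of 30 lysosome and MiT/TFE genes to rise, none fell, and 1 passed limma adjusted over the list alone. Of 27 genes in the unfolded protein and amino acid response list, only Ddr2 rose (8.03-fold). It encodes a collagen receptor, so its rise by itself is no sign of that response. The cystathionine lyase gene Cth was 4.11-fold lower (limma adjusted p = 0.0971), and 4 members passed limma adjusted over the list alone. No member rose or fell among 20 cholesterol biosynthesis genes (Hsd17b7 2.22-fold lower, limma adjusted p = 0.0526), 28 glycolysis and hypoxia genes (Pdk1 2.04-fold higher, limma adjusted p = 0.0561) or 23 heme and iron genes (the iron exporter gene Slc40a1 3.12-fold lower, limma adjusted p = 0.115). Adjusted over the list alone, limma passed 3, 3 and 0 members of these lists. Their median differences were 0 and -0.03, 0.01 and 0.06, and 0 and 0 in clones 4 and 10, and those of the lysosome and unfolded protein lists were 0 and 0, and -0.00444 and -0.28. The unfolded protein list's median lay at percentile 2.88 in clone 4 and 0 in clone 10, with 14 members below mock in both clones and 6 above. Its mean was 0.03 in clone 4 and -0.23 in clone 10, at percentiles 60.8 and 1.07. Ddr2 (2.94 in clone 4 and 3.07 in clone 10) raises this mean, and Cth (-1.82 and -2.26) lowers it.

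Among markers of mammary and other cell types, 2 genes rose and none fell. Of 18 luminal markers, the pioneer factor gene Foxa1 rose 7.73-fold (limma adjusted p = 0.0439, and 0.0664 in the planned test after a second quantile normalization), none fell, and 2 passed limma adjusted over the list alone. Krt18, a luminal keratin gene that the epithelial list also holds, was 1.93-fold lower (limma adjusted p = 0.0972). None of 18 basal and myoepithelial markers was 2-fold apart in both clones, and Krt14 was 1.67-fold lower (limma adjusted p = 0.0913). Pdgfrb was the 1 member of 19 fibroblast markers to rise, with Dcn 3.91-fold lower (limma adjusted p = 0.0711). Of 18 endothelial markers, Flt1 was 3.79-fold higher (limma adjusted p = 0.144), and of 22 immune markers, Cd74 was 3.16-fold higher (limma adjusted p = 0.153) and Cd14 4.20-fold lower (limma adjusted p = 0.0907), so that none rose or fell in either list. Adjusted over the list alone, limma passed 0 basal, 2 fibroblast, 0 endothelial and 0 immune markers. Members above mock in both clones outnumbered those below in the immune list (10 to 1), the endothelial list (9 to 1), the fibroblast list (11 to 4) and the luminal list (10 to 4), but not in the basal list (4 to 5). These counts include differences of any size and genes of low signal. The immune list's median was 0 in clone 4 and 0.06 in clone 10, at percentiles 37.9 and 99.3. The medians of the luminal, fibroblast and endothelial lists lay at percentiles 90.2, 84.4 and 61.3 in clone 4 and 91.9, 95.2 and 96.0 in clone 10. With low genes left out, 4 immune, 4 endothelial, 8 fibroblast and 8 luminal markers remained. Their medians then lay at percentiles 68.3, 79.9, 92.3 and 23.2 in clone 4. In clone 10 they lay at percentiles 84.6, 81.1, 95.4 and 12.5, and none of these lists stood apart. After a second quantile normalization the endothelial median was -0.02 in clone 4 and 0.02 in clone 10.

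**Figure D2:**
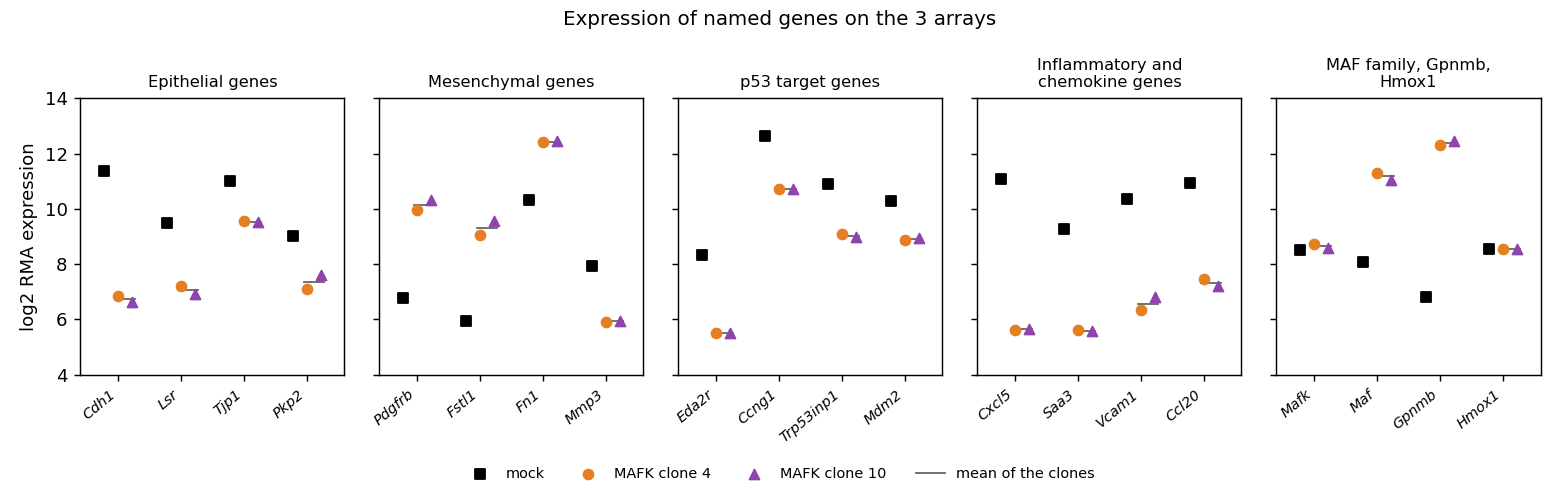
Log2 RMA expression of 20 named genes on the mock array (black squares), the clone 4 array (orange circles) and the clone 10 array (purple triangles), with a grey line at the mean of the clones. Cdh1 lies at 11.35 in mock and near 6.75 in the clones, Gpnmb at 6.82 and near 12.39, and Hmox1 at 8.56 on all 3 arrays.

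**Figure D3:**
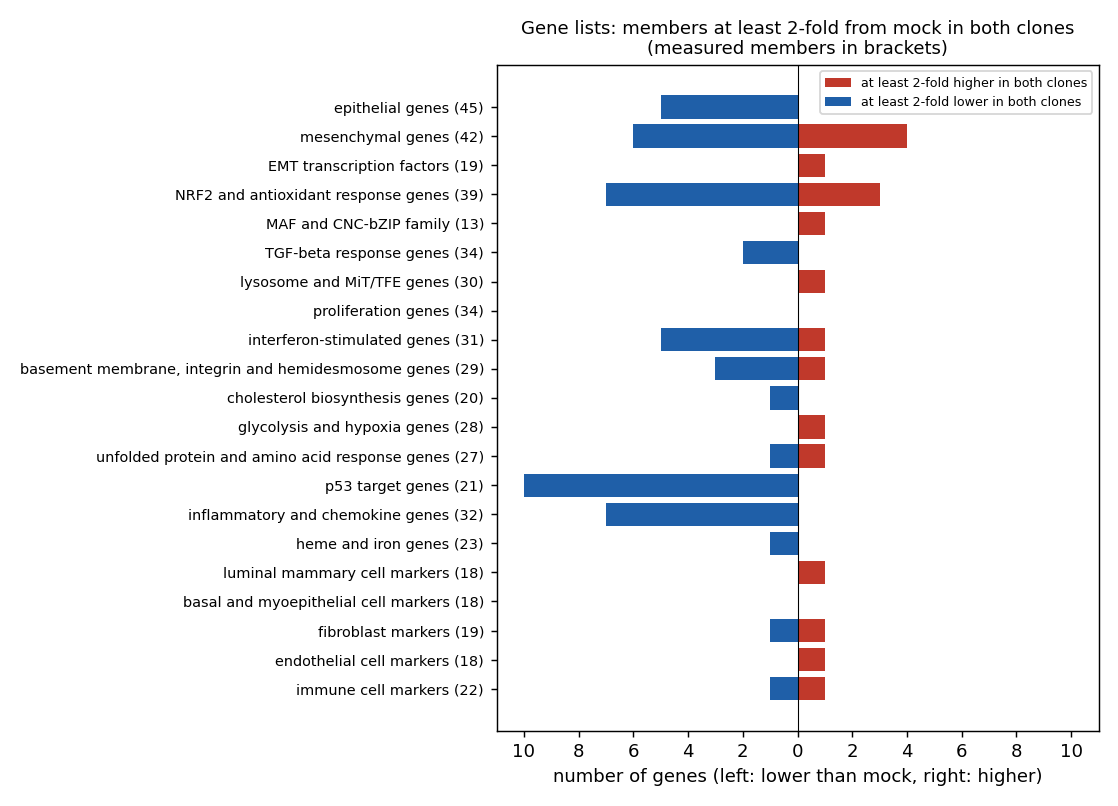
Number of members of each of 21 gene lists that were at least 2-fold higher (red, to the right) or lower (blue, to the left) than mock in both clones, with the number of measured members in brackets. The p53 list has the most lower members, 10 of 21, and the mesenchymal list has 4 higher and 6 lower members of 42.

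Clone 4 and clone 10 were each compared with mock to ask how alike the profiles of separate clones were. Gpnmb was higher by 5.50 in clone 4 and 5.64 in clone 10 on the log2 scale, and Cdh1 differed by -4.50 and -4.71. In clone 4, 753 genes were at least 2-fold apart from mock, 305 higher and 448 lower. In clone 10, 715 genes were, 291 higher and 424 lower. Of the higher genes, 237 were shared, which is 77.7% of clone 4's and 81.4% of clone 10's, and of the lower genes 361 were shared, 80.6% and 85.1%. With 1 array on each side these differences have no replicate and no test.

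The log2 differences of the clones from mock correlated across genes with a Pearson r of 0.937 and a Spearman rho of 0.858. Genes are not independent replicates, and both differences share the mock array: simulated clones with no effect gave a mean r of 0.502 and rho of 0.444. The covariance was 0.190 against 0.0128 simulated, a difference of 0.178. Independent lists of the same sizes would share 4.45 higher and 9.53 lower genes, and the simulation without effect shared at most 20 in either direction. The mock array could not be split, so part of the overlap above these values may come from the shared array.

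Clone 10 was compared with clone 4 to measure the spread between lines that carry the same transgene. The imprinted gene Peg3 differed most, 6.63-fold higher in clone 10, and it was the 1 gene at least 2-fold apart from mock in opposite directions, -1.45 in clone 4 and 1.28 in clone 10 on the log2 scale. The carbonic anhydrase gene Car13 was 5.90-fold lower in clone 10 and the glutathione transferase gene Gstt1 4.71-fold lower. Mustn1 was 4.12-fold higher and the sulfatase gene Sulf2 4.06-fold higher in clone 10, and the desmosomal cadherin gene Dsg2 was 3.62-fold lower. In all, 88 genes were at least 2-fold apart, 44 higher and 44 lower in clone 10, against 753 and 715 between the clones and mock. These genes were named after their values were seen, and single arrays allow no test.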

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

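The tests on identical values were chosen after the result was seen. Outside the named genes, 103 probe sets with no gene symbol or with several were at least 2-fold apart from mock in both clones, a signal in measurements that the comparisons of genes did not use. Of these, 22 were higher and 81 lower, and they made up 1.46% of 7035 such probe sets, against 598 of 19935 genes. Some of the lower ones had equal or nearly equal values to one another on each array, so the 103 are not separate signals. No explanation for these probe sets was tested.

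The equal values on all 3 arrays in 35.9% of probe sets were weighed as a pattern because they decide what a test can show. A floor or filter on low signals is argued against, since 33.3% of the equal probe sets lay above the median of all probe sets. Median polish over only 3 arrays may be the source: simulated probe sets without change came out equal in 78.1% of cases with 3 arrays and in 0% with 6. No biological explanation was tested for this pattern.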

How the results depend on the processing

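The limma fit with another prior, the fit on genes whose clones differ, list means and the count without chromosomes 8, 14 and X were chosen after the results were seen. Limma as planned passed 3553 genes (2240 higher, 1313 lower), against 334 with treat at a fold of 1.2, 6348 at an unadjusted p, 581 among genes whose clones differ, and 232 with the prior of those genes. Centring each array on its median passed 12059 genes (2927 higher, 9132 lower), because it gave genes with equal values a small and nearly equal difference in both clones. Genes apart in both clones numbered 1230 at 1.5-fold and 287 at 3-fold, those of clone 4 against mock 1553 and 380, those of clone 10 against mock 1521 and 346, and those between the clones 291 and 15. Without 1 clone, between 715 and 753 genes were 2-fold apart in the other, 5 to 7 lists stood apart, and 19 to 20 of the 24 genes ranked first were shared. Of the gene lists, 4 stood apart (proliferation higher, and p53, interferon and TGF-beta lower), 7 with low genes left out (also epithelial, NRF2 and inflammatory, lower) and 8 by list means (these 7 and MAF, higher), and the 4 were shared in each. The MAF list's mean rests largely on Maf itself (3.19 in clone 4 and 2.97 in clone 10). Its median was 0.02 in each clone, and 6 of its 13 members had equal values on all arrays. The NRF2 list also stood apart after a second quantile normalization and without chromosomes 8, 14 and X, and the unfolded protein list against unmatched random lists. The cause was not tested. Without chromosomes 8, 14 and X, 516 genes were apart in both clones, and the correlation of the clones stayed between 0.937 and 0.939 in the settings run. Leaving out these chromosomes keeps several others whose mean differences were also shifted in both clones. No named gene reversed. Against limma as planned, over genes and settings, 739 values kept their side of the threshold, 80 lost it and 15 gained it. Values of the added fit, which defines "rose" and "fell", are not given under these settings, so the counts do not test those calls directly. In the planned limma test on the values as deposited, adjusted p-values of Pdgfrb, Sox9, Maf, Foxa1, Ephx1 and Ccl20 ran from 0.0281 (Ccl20) to 0.0371 (Pdgfrb). These 6 genes, in that order, lost it both with a second quantile normalization and with low genes left out, at adjusted p-values of 0.0717 and 0.0939, 0.0610 and 0.0693, 0.0580 and 0.0637, 0.0664 and 0.0878, 0.0683 and 0.0859, and 0.0556 and 0.0591. Hmox1, equal on all arrays, differed by -0.03 after centring and by 0.03 after a second quantile normalization. No paired analysis was possible because the groups share no replicate numbers. Robust estimation in eBayes gave no value, and the reason was not tested. The mock array cannot be left out, and leaving out a clone leaves 1 array against 1 and no test. Signal over background was not given per probe set, so how far low values limit folds is unknown.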

Other observations

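All tests on chromosomes and X-linked genes in this part were chosen after the results were seen, except the test of genes that escape X silencing, which was set before its values were seen. X-linked genes were apart in both directions. Of 739 X-linked genes, 33 (4.47%) were at least 2-fold apart from mock in both clones, against 565 of 19196 others (2.94%), an odds ratio of 1.54 with a two-sided Fisher's exact p of 0.0270 that treats genes as independent, which they are not. Besides Dynlt3 and Praf2, 13 were higher, among them the peroxiredoxin gene Prdx4 (9.22-fold), the kinase gene Pak3 (9.02-fold) and Apln, which encodes the peptide apelin (8.49-fold). Besides Xist and Fundc2, 16 were lower, among them the vesicle fusion gene Vamp7 (-3.80 on the log2 scale), Pir (7.96-fold), Vsig1 (6.88-fold) and Vegfd (4.20-fold).

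Genes of chromosome 14 were lower and genes of chromosome 8 higher as whole sets. The median difference of 254 chromosome 14 genes with a mean log2 value of at least 8 was -0.37 in clone 4 and -0.20 in clone 10, and 70.1% were lower in both clones, against at most 52.1% on any other chromosome (12). On chromosome 8 the median of 468 genes was 0.16 in clone 4 and 0.15 in clone 10, and 66.5% were higher in both. By their mean differences, chromosomes 1, 9, 10, 12, 13, 14 and 18 lay below percentile 2.5 of random sets of as many expressed genes in both clones, and chromosomes 2, 5, 8, 11 and 16 lay as far up the other end. Between the clones, the medians of clone 10 minus clone 4 were 0.16 on chromosome 14 and -0.07, -0.07 and -0.06 on chromosomes 6, 17 and 19.

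One scaling of each whole array would move all chromosomes the same way, and is argued against by the chromosome 8 medians of 0.164 in clone 4 and 0.147 in clone 10, opposite in sign to those of chromosome 14. A few strongly altered genes are argued against too, since 70.1% of the chromosome 14 genes were lower in both clones, above every other chromosome. Another number of copies of chromosome 14 in the clones than in mock stays open and untested, since the 70.1% is the observation that prompted it and DNA was not measured here. MAFK expression itself stays open too, because no clone without the transgene was measured, and the clones' chromosome 14 medians differed by 0.171.

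For the X-linked genes, a lower dose of the active X chromosome is argued against by a median difference of 0 over expressed X-linked genes in each clone. Losing 1 of 2 equally active copies would lower a gene about 2-fold, though the activity of each copy was not measured. On that premise, loss of the inactive X chromosome is argued against for 11 of the 17 lower genes other than Xist. These 11 were at least 3-fold lower in both clones. Nor would that loss by itself account for the 15 X-linked genes that were higher. For Xist and the other 6 lower genes it stays open. A set of 5 genes known to escape silencing had medians of -0.0639 in clone 4 and -0.0295 in clone 10. These lay above the -0.1 set beforehand as evidence against, but by less than the spread of the genes. Their mean differences were -0.59 for Eif2s3x, -0.30 for Kdm6a, -0.03 for Ddx3x, -0.03 for Kdm5c and 0 for Pbdc1. Another choice of escaping genes could move such medians past -0.1, so they do not decide the question. Descent of both clones from a subpopulation unlike the mock cells might also give this pattern: 7 X-linked genes were 2-fold apart between the clones, against 39 and 35 between each clone and mock. An effect of MAFK on these genes cannot be told apart from that descent with 1 mock array.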
